A study of Homo sapiens with 18 samples.

How the data were processed

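Gene expression was measured on 18 one-colour CodeLink Human Whole Genome arrays, with 1 biotin-labelled cRNA sample per slide and bacterial RNA spikes added to each sample. Per the labels, 12 arrays came from T-HESC, a stromal line of human endometrium immortalized with telomerase, and 6 from U-937, a human monocytic line turned into macrophages with 32 nM phorbol myristate acetate for 48 h. T-HESC cells received vehicle (0.1% ethanol) or hormone (estradiol at 10 nM with the synthetic progestin medroxyprogesterone acetate at 100 nM) for 8 days, without serum from day 6. Part of each set also received medium conditioned by U-937 macrophages for the final 24 h. The macrophages received non-conditioned control medium or T-HESC-conditioned medium for 24 h. Each of the 6 groups held 3 arrays, numbered by cell passage (9, 11 and 13 for T-HESC; 7, 9 and 11 for U-937). The sources used here do not say which control medium the T-HESC cells without macrophage-conditioned medium received, and they differ on the last U-937 passage and on the serum share. Total RNA input was 1 µg for T-HESC and 2 µg for macrophages, so the cell lines were normalized and fitted apart. Levels were set against each other between the lines only in a test of macrophage RNA carried over with the medium, on the deposited normalized intensity, which makes its shares approximate.

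The deposited scanner exports give each spot as fluorescence intensity, from CodeLink Expression Analysis 5.0.0.31312 per the file headers. The authors' raw intensity equals the spot mean minus the median of its local background on every unmasked spot, to within 0.0001. Their normalized intensity, also deposited, is that intensity divided by the median of the array, and the deposited series table holds identical values (largest difference 0). Each export holds 53423 discovery probes and 936 control probes. Gene symbols came from the platform annotation (22824 probes), from the gene number in the export (13214) or from the export's symbol (375); 905 probes with several genes, 648 with differing sources and 15457 without a name stayed unnamed in the gene lists. In all, 4881 probes match several public transcripts per the exports and were kept, among them those used for TSC22D3, HSD11B1, IL32, SOD2, CHI3L2, TP53I3, LTBP1, NMB, ZWINT, MCM4, DUT, CXCL2, PLPP1, ANGPTL4, CD163, IGFBP1 and FN1. No genomic coordinates were used.

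Spot means were background-corrected with normexp (offset 50), log2-transformed and quantile-normalized within each cell line, after spots marked masked, irregular or contaminated had been removed. A probe was tested when it was marked above background on all 3 arrays of at least 1 group and had values on at least 2 arrays of every group. This left 33851 probes (15818 named genes) for T-HESC and 30694 probes (14955 named genes) for the macrophages. A linear model with 1 mean per group was fitted to each probe with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with data.table (version 1.17.8). Adjusted p values are Benjamini-Hochberg values over the tested probes of 1 comparison, two-sided, and a probe was called at an adjusted p under 0.05. Fold changes are given as log2 with the standard error of the model (SE, n = 3 arrays per group unless another number is given). Where every array of the lower group was not above background, only the bound that the background level allows is given, as "at least". Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 read the exports, and matplotlib 3.10.9 drew the figures.

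The comparisons were the hormone effect without and with macrophage-conditioned medium, the effect of that medium without and with hormone, the interaction of both, the mean effect of each treatment, and the effect of T-HESC-conditioned medium on macrophages. Passage number was left out of the model and tried as a block. Between groups, residuals of T-HESC arrays with the same passage number correlated with a median of 0.129 over 18 pairs (-0.0397 over the 36 other pairs), and those of macrophage arrays between -0.0494 and 0.0900 over 3 pairs. A gene with several probes was represented by its brightest tested probe, and other probes are named where they gave the opposite call.

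The genes named in the text followed a rule fixed before the data were examined, as were the comparisons, the filter, the model, the gene lists and the alternatives not described as added later. For the hormone effect without medium, the macrophage medium effect without hormone and the macrophage comparison, the rule took the 10 largest rises and 10 largest falls among called probes with 1 gene symbol, with all 3 arrays of 1 group on 1 side of the other 3 and above background on all 3 arrays of the higher group. For the other comparisons it took 5 of each; the interaction had no separation rule, and the mean effects required separation within each stratum. It added up to 4 called members of each gene list, or 2 with the smallest p where none was called, and a set of reporter genes. Of the reporters, GREB1 was above background on 0 of 12 T-HESC arrays, MRC1 on at most 4 of 6 macrophage arrays, and CXCL1, IL1B and APOE had no probe named for a single gene.

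Altogether 29 gene lists were tested, 24 for pathways and 5 for cell type markers, on the brightest probe of each gene. The pathway lists covered steroid hormone receptors, decidualization markers, progestin and glucocorticoid receptor targets, estrogen receptor targets, metallothioneins, chemokines, inflammatory cytokines and growth factors, NF-kB feedback and target genes, interferon-stimulated genes, matrix metalloproteinases with their inhibitors and the plasminogen system, extracellular matrix structure, contractile and TGF-beta response genes, cell cycle genes, cholesterol synthesis, LXR targets, the amino acid and ER stress response, hypoxia and glycolysis, immediate early genes, angiogenic factors, the NRF2 response, classically and alternatively activated macrophage genes, MHC class II, and lysosome and phagocytosis. The list called LXR targets here also held genes of lipid handling, among them PPARG, FABP4, FABP5 and OLR1. The marker lists covered macrophages and leukocytes, stromal fibroblasts, epithelium, endothelium and undifferentiated myeloid cells. List p values came from limma's camera with a preset correlation of 0.01 between genes, adjusted over the 29 lists of 1 comparison. They were repeated with the correlation estimated for each list and with fry, a rotation test of whether the genes of a list move on balance 1 way.

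The method was tested on simulated data built from each cell line's values, with 200 probes changed by 0.5, 1 or 2 on the log2 scale in 5 runs. For the hormone effect without medium (33851 probes) it recovered 89.9% of changes of 0.5 and 100% of changes of 1 and 2, with 7.12% false calls. For the interaction it recovered 38.2% at 0.5 and 99.7% at 1, with 6.82% false calls. In the macrophages (30694 probes) it recovered 63.9% at 0.5 and 99.7% at 1, with 7.58% false calls. Each of these shares of false calls lay above the share that the threshold of 0.05 allows. The recovery holds for the simulated changes and was not measured on real ones. On the macrophage arrays some values above 1, among them those of FN1 and MT1X, were not called, so recovery there can be lower than simulated.

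Alternatives changed the background correction, offset, normalization, filter, spot flags, variance model, array weights, arrays in the fit, probe choice and threshold, used the deposited normalized intensity, added the passage block, or left out each array in turn. Added after the data were seen were scaling of the T-HESC arrays to the bacterial spikes, the macrophage fit without control replicate 1 combined with the passage block, the list tests and the overlap of calls without that array, and the overlap in opposite directions. The series table was not run as an alternative, because its values are those of the normalized intensity. A block for slide or scan was not run, because each of the 3 runs of slide numbers held either the macrophages, the T-HESC arrays without macrophage-conditioned medium, or those with it. The hormone comparisons lie within runs, while the medium and the run cannot be told apart by the design.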

Results

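The arrays covered both directions of exchange between endometrial stromal cells and macrophages, and the stromal response to estrogen with a progestin. T-HESC cells formed 4 groups of 3 arrays, which received vehicle, hormone, macrophage-conditioned medium, or both. U-937 macrophages formed 2 groups of 3 arrays, with control medium or T-HESC-conditioned medium. The share of discovery probes above background was 58.8% to 64.2% on the T-HESC arrays and 56.8% to 62.9% on the macrophage arrays. Median raw intensity was 34.1 to 47.0 and 32.8 to 42.8, respectively. Macrophage control replicate 1 stood apart, with correlations across tested probes of 0.973 to 0.979 with the other macrophage arrays, which correlated at 0.987 to 0.995 with each other. The number of arrays, 3 per group, limits the precision of every value.

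The first question was how stromal cells responded to estradiol with the progestin when no macrophage medium was present. CORIN, which encodes a protease that activates natriuretic peptides, rose the most among genes named by rule (log2 fold change 2.58, SE 0.11, 5.97-fold, probe GE80568, limma adjusted p = 5.07e-11). TSC22D3, a leucine zipper gene classically induced through glucocorticoid and related steroid receptors, rose by 2.17 (SE 0.12, n = 3 per group). INHBB, which encodes an activin and inhibin subunit, rose by 2.45 (SE 0.15), and IGFBP2, which encodes a binding protein of insulin-like growth factors, by 2.36 (SE 0.13). AOX1, for aldehyde oxidase, rose by 2.46, the less characterized PWWP3B by 2.48, and the matrix protein gene PAPLN by 2.30. FLJ14054 (1.92), the adrenergic receptor gene ADRA2C (1.83) and the matrix proteoglycan gene OMD (1.75) completed the 10 largest rises. NPTX1, which encodes a pentraxin of synapses, fell the most, by 3.45 (SE 0.12, probe GE59285, adjusted p = 6.23e-12). The transcription factor gene ETV1 (-2.52), DOCK2 (-2.21), SIPA1L2 (-2.05) and the lysyl oxidase family gene LOXL4 (-2.00) followed. HBD (-1.85), FJX1 (-1.83), PLXDC2 (-1.65), HTR2B (-1.53) and the WNT antagonist gene DKK2 (-1.50) were the other large falls.

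Genes that progestins and glucocorticoids induce through their receptors rose as a group. Of 25 tested progestin and glucocorticoid receptor targets, 11 rose, 0 fell and 14 were not called (12 and 0 adjusted over the list alone; camera adjusted p = 1.51e-11, adjusted p = 0.00319 with an estimated correlation). They included HSD11B1, which encodes the enzyme that makes cortisol from cortisone (1.38, SE 0.09), and IMPA2 (1.59). FKBP5, a co-chaperone of steroid receptors, gave differing values by probe: its brightest probe was not called (-0.09, adjusted p = 0.713), while GE562546 and GE543138 rose by 1.60 and 1.09 and GE619043 was not called (-0.25). ZBTB16 (0.18, adjusted p = 0.147) and MAOA (0.14, adjusted p = 0.362) were not called.

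Among 28 decidualization markers, 11 rose and 1 fell (13 and 3 adjusted over the list alone; camera adjusted p = 4.86e-05, adjusted p = 0.0128 with an estimated correlation). FOXO1, a transcription factor of decidual differentiation, rose by 0.76 (SE 0.11). PRL, the prolactin gene and a classical decidual marker, rose by 0.37 (SE 0.09, adjusted p = 0.0108, 2 of 3 vehicle arrays with values). That call was lost without vehicle replicate 2, at an adjusted p of 0.0703 in a range of 0.00382 to 0.0703 over its alternatives. IGFBP1, another classical marker, was not called (-0.04, adjusted p = 0.719). Of 9 steroid hormone receptor genes 2 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 0.749). PGR, the progesterone receptor gene, fell by 0.84 (SE 0.14) and ESR1, the estrogen receptor alpha gene, fell by 0.36 (SE 0.10, adjusted p = 0.0185). The ESR1 call was lost without vehicle replicate 2 (0.0798), hormone replicate 1 (0.0922) or hormone replicate 2 (0.0732), within a range of 0.00547 to 0.0922. Of 16 estrogen receptor targets 2 rose and 7 fell (2 and 8 adjusted over the list alone; camera adjusted p = 0.23).

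Cell cycle genes were lower with hormone. Of 51 tested, 36 fell and 0 rose (40 and 0 adjusted over the list alone), with a median of -0.54. Cyclin genes CCNB1 (-1.05, SE 0.12), CCNB2 (-0.89) and CCNA2 (-0.89) and the spindle gene TPX2 (-0.95) were among them. The list passed camera with the preset correlation (adjusted p = 4.63e-18) but not with an estimated one (adjusted p = 0.137 with an estimated correlation). Alternatively activated macrophage genes also passed with the preset correlation, with 3 of 33 higher and 1 lower, also adjusted over the list alone (adjusted p = 0.0288; adjusted p = 0.133 with an estimated correlation).

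Matrix and signalling genes moved both ways. Of 25 genes of matrix metalloproteinases, their inhibitors and the plasminogen system 8 rose and 6 fell (11 and 7 adjusted over the list alone; camera adjusted p = 0.263). The collagenase gene MMP1 fell by 1.35 (SE 0.18). Of 41 extracellular matrix genes 10 rose and 6 fell (11 and 6 adjusted over the list alone; adjusted p = 0.426), with COL5A2 up by 0.98 and LUM and DCN at -0.75 and -0.76. Of 29 immediate early genes 3 rose and 8 fell (3 and 10 adjusted over the list alone; adjusted p = 0.14), among them DUSP6 (-1.15) and IER3 (-1.06), while EGR3 was at least 1.47-fold lower. Of 40 interferon-stimulated genes 4 rose and 11 fell (4 and 13 adjusted over the list alone; adjusted p = 0.146), with IFIT3 at -0.50 and OAS2 at 0.52. Of 23 cholesterol synthesis genes 0 rose and 6 fell (1 and 7 adjusted over the list alone; adjusted p = 0.23). Chemokine genes had 0 rises and 2 falls among 17 (adjusted p = 0.556), with CXCL12 at -0.81. The median, the mean and the test differed in sign for epithelial markers, NF-kB targets, extracellular matrix genes, LXR targets, the NRF2 response and endothelial markers.

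Altogether 1959 probes rose and 2729 fell of 33851 (13.8%), or 1031 and 1503 genes. The count of 4688 dropped to 2789 without vehicle replicate 1, 2678 without vehicle replicate 2 and 2312 without hormone replicate 2. The share of rises among the calls depended on the processing and the threshold, which changed the probes that were called. Rises made up 41.8% of the calls, 26.3% with the deposited normalized intensity, 54.1% at a log2 change of at least 1 and 74.7% (354 of 474) with scaling to the spikes.

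**Figure D1:**
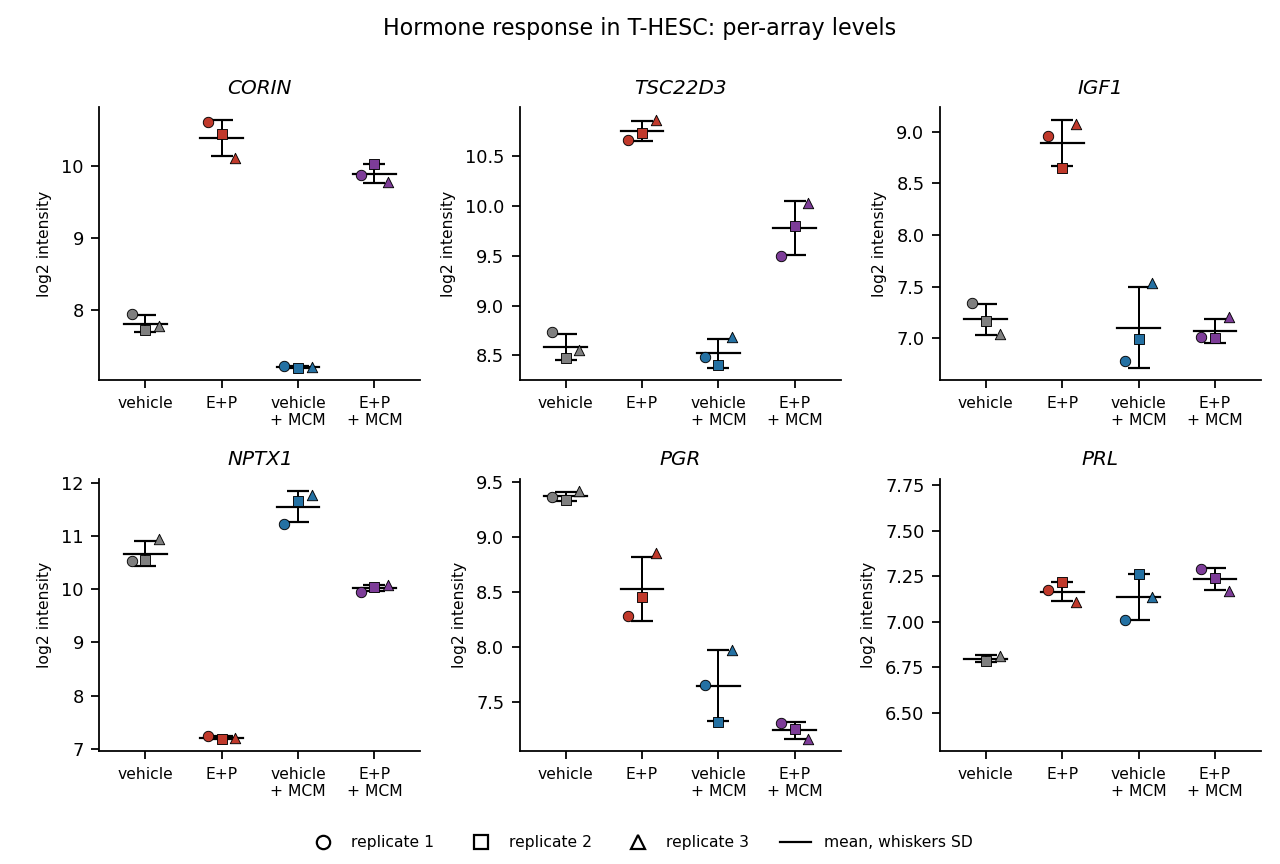
Log2 normalized intensity of 6 genes in the 4 T-HESC groups, with 1 point per array (shapes mark replicates), lines at the means and whiskers of 1 SD. CORIN and TSC22D3 were higher with hormone in both media, NPTX1 was lower, and the interaction of IGF1 was -1.74, with a higher level under hormone when no macrophage-conditioned medium was given.

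The same hormone comparison was made in cells that also received macrophage-conditioned medium. CHI3L2, a chitinase-like gene, rose by 3.45 (SE 0.16, 10.9-fold, probe GE62928, adjusted p = 4.81e-10), and PTX3, which encodes a soluble pentraxin of innate immunity, by 2.78 (SE 0.25, probe GE79481). CORIN and INHBB rose here too, by 2.69 (SE 0.11) and 2.67 (SE 0.15), and the monocyte chemokine gene CCL8 rose by 2.34 (SE 0.19), with 2 of 3 arrays without hormone above background. F2RL1, which encodes a protease-activated receptor, fell by 2.39 (SE 0.10) and MMP1 fell by 2.16 (SE 0.18). The carboxypeptidase inhibitor gene LXN (-2.06), the BMP co-receptor gene RGMB (-2.01) and TP53I3 (-1.79) also fell. Of the progestin and glucocorticoid receptor targets 11 rose and 1 fell (12 and 1 adjusted over the list alone; adjusted p = 1.72e-07, adjusted p = 0.0145 with an estimated correlation), with HSD11B1 at 1.66, IMPA2 at 1.79 and TSC22D3 at 1.26. On FKBP5, the brightest probe was not called (-0.27, adjusted p = 0.349).

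Chemokine genes were higher with hormone in the presence of the medium, with 4 of 17 rising and 0 falling (6 and 0 adjusted over the list alone; adjusted p = 0.00072, adjusted p = 0.02 with an estimated correlation). CXCL2, which attracts neutrophils, rose by 1.62 and CCL5 by 1.21. Of 23 genes on the list of LXR targets and lipid handling 7 rose and 0 fell (9 and 0 adjusted over the list alone, camera adjusted p = 6.81e-05, adjusted p = 0.02 with an estimated correlation), among them PPARG (0.85), FABP4 (0.77) and MYLIP (0.70). The NRF2 response had 3 rises and 0 falls among 21 (6 and 0 adjusted over the list alone; adjusted p = 0.000424, adjusted p = 0.02 with an estimated correlation), including GCLC (0.67). Alternatively activated macrophage genes had 6 rises and 1 fall among 33 (7 and 2 adjusted over the list alone; adjusted p = 0.000833, adjusted p = 0.02 with an estimated correlation), including the scavenger receptor gene CD163 (1.18, with 2 of 3 arrays without hormone above background).

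Cell cycle genes fell again, 28 of 51 with 0 rises (37 and 0 adjusted over the list alone; adjusted p = 1.06e-20, adjusted p = 0.0558 with an estimated correlation), including CCNB1 (-0.83), AURKB (-0.82) and KIF2C (-0.85). Calls that also ended with an estimated correlation were those of metallothioneins (2 of 5 higher and 0 lower, also adjusted over the list alone; adjusted p = 0.013, adjusted p = 0.0558 with an estimated correlation) and decidualization markers (5 higher and 3 lower, 7 and 4 adjusted over the list alone; adjusted p = 0.0256, adjusted p = 0.0558 with an estimated correlation). Interferon-stimulated genes (2 higher and 8 lower, 3 and 11 adjusted over the list alone; adjusted p = 0.0278, adjusted p = 0.0558 with an estimated correlation) and cholesterol synthesis genes (1 higher and 1 lower, 3 and 1 adjusted over the list alone; adjusted p = 0.0163, adjusted p = 0.212 with an estimated correlation) were the others. MT1X rose by 1.06, IFIT3 fell by 0.82 and SAMD9 fell by 0.71. FOXO1 (0.11), PRL (0.10), IGFBP1 (0.15), ESR1 (-0.20), ZBTB16 (0.23), MAOA (-0.02) and IGF1 (-0.03, adjusted p = 0.945) were not called. PGR was not called either (-0.40, adjusted p = 0.0997), but passed with the passage block (0.0403), with array weights (0.0321) and without medium replicate 2 (0.0127), within 0.0127 to 0.376 over its alternatives.

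In all, 966 probes rose and 1181 fell with hormone in the presence of the medium (6.34%), or 591 and 787 genes. The count of 2147 dropped to 1379 without medium replicate 1 and 1413 without replicate 2 of hormone with medium. Across the 33851 probes the hormone log2 fold changes in the absence and presence of the medium correlated with Pearson r 0.464 and Spearman rho 0.364, over probes that are not independent replicates. Of 989 probes called in both, 943 moved the same way, where 151.1 would be expected if calls were independent. Rises were 45% of these calls, 34.5% with median scaling and 26.9% with scaling to the spikes.

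The effect of macrophage-conditioned medium on stromal cells was first measured without hormone. CXCL8, which encodes a neutrophil chemokine, rose by 5.50 (SE 0.15, 45.1-fold, probe GE62180, adjusted p = 2e-14). CEMIP, which encodes a hyaluronan-degrading protein, rose by 4.70 (SE 0.12), and the stromelysin gene MMP3 by 4.68 (SE 0.25, probe GE79854, 2 of 3 vehicle arrays with values). The collagenase gene MMP1 rose by 3.63 (SE 0.18), the cytokine genes IL32 and IL33 by 3.66 and 3.31, and HSD11B1 by 3.53 (SE 0.09). SOD2, the mitochondrial superoxide dismutase gene, rose by 3.46 (SE 0.09), while another of its probes fell slightly (-0.23, adjusted p = 0.0176). PLN, for the calcium pump inhibitor phospholamban, rose by 3.38 with 1 of 3 vehicle arrays above background. OSR2, a transcription factor gene, fell the most, by 3.10 (SE 0.10, probe GE87626). The transcription factor gene KLF4 fell by 2.65 (SE 0.13), followed by SIPA1L2 (-2.62), the retinoic acid binding protein gene CRABP2 (-2.35) and ADGRL3 (-2.32). CABCOCO1 (-2.24), TBC1D8 (-2.14), ANGPTL4 (-2.12), AMOT (-2.06) and PLPP1 (-2.02) were the other large falls.

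Inflammatory gene groups rose. Of 31 NF-kB feedback and target genes 16 rose and 2 fell (17 and 3 adjusted over the list alone; adjusted p = 5.04e-05, adjusted p = 0.0287 with an estimated correlation), with NFKBIZ up by 1.15 and BIRC3 at least 1.86-fold higher. Cytokine and growth factor genes had 9 rises and 2 falls among 18 (10 and 2 adjusted over the list alone, camera adjusted p = 0.000369, adjusted p = 0.0287 with an estimated correlation), including IL6 (1.17, SE 0.09). The activin subunit gene INHBA, on the list of contractile and TGF-beta response genes, rose by 2.39. Of 17 chemokine genes 7 rose and 0 fell (11 and 1 adjusted over the list alone; adjusted p = 0.00397, adjusted p = 0.0493 with an estimated correlation), with the monocyte chemokine genes CCL2 at 1.35 (SE 0.22) and CCL7 at 1.30. Of 22 genes of classically activated macrophages 8 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.00397, adjusted p = 0.0493 with an estimated correlation). The metalloproteinase and plasminogen list had 13 rises and 4 falls (14 and 5 adjusted over the list alone; adjusted p = 0.000762, adjusted p = 0.0287 with an estimated correlation), with SERPINB2 up by 3.16 and 1 of 3 vehicle arrays above background. The adhesion gene ICAM1 rose by 0.57. MMP10 rose by 0.28 (adjusted p = 0.0185), a call lost without vehicle replicate 1 (0.0588) or medium replicate 2 (0.0818) and with the deposited normalized intensity (0.434), over alternatives from 0.0079 to 0.434. LIF fell by 0.27 (adjusted p = 0.0241), a call lost without vehicle replicate 2 (0.113), vehicle replicate 3 (0.0770) or medium replicate 1 (0.112), in a range of 0.00464 to 0.113. TNFAIP6 (-0.02), PTGS2 (-0.08), VEGFA (-0.08) and MX1 (0.04) were not called.

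Several further lists passed with the preset correlation only. Cell cycle genes had 27 rises and 0 falls (28 and 0 adjusted over the list alone; adjusted p = 3.12e-05, adjusted p = 0.276 with an estimated correlation), among them the ribonucleotide reductase genes RRM2 (1.24) and RRM1 (0.80). Contractile and TGF-beta response genes had 11 rises and 2 falls among 22 (13 and 2 adjusted over the list alone; adjusted p = 0.000333, adjusted p = 0.114 with an estimated correlation), with CCN2 at 3.03 and CCN1 at 2.43. Hypoxia and glycolysis genes had 14 rises and 5 falls among 33 (16 and 5 adjusted over the list alone; adjusted p = 0.0149, adjusted p = 0.247 with an estimated correlation), such as LDHA (1.42) and HK2 (1.38). Cholesterol synthesis genes had 12 rises and 3 falls, also adjusted over the list alone (adjusted p = 0.0167, adjusted p = 0.216 with an estimated correlation), with STARD4 at 1.37. Immediate early genes had 12 rises and 4 falls (13 and 4 adjusted over the list alone; adjusted p = 0.0117, adjusted p = 0.193 with an estimated correlation). Metallothioneins had 2 rises and 0 falls (3 and 0 adjusted over the list alone; adjusted p = 0.0149, adjusted p = 0.093 with an estimated correlation), and MHC class II genes 6 rises and 1 fall among 13 (7 and 1 adjusted over the list alone; adjusted p = 0.0326, adjusted p = 0.114 with an estimated correlation). Lower were the amino acid and ER stress response, with 4 rises and 15 falls among 30 (5 and 16 adjusted over the list alone; adjusted p = 0.000747, adjusted p = 0.232 with an estimated correlation), and LXR targets, with 5 rises and 12 falls (adjusted p = 0.0102, adjusted p = 0.0866 with an estimated correlation). The serine and asparagine synthesis genes PSAT1 (-1.94) and ASNS (-1.70), the stress gene DDIT3 (-1.64) and the LXR target MYLIP (-1.36) were among the falls.

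Lists of hormone reception and stromal differentiation were not called, and their members moved both ways. PGR fell by 1.72 (SE 0.14) and the homeobox gene HOXA10 fell by 1.40 (SE 0.14), and HAND2 (-1.56) and TWIST1 (-1.21) were lower too. Of 9 steroid hormone receptors 1 rose and 3 fell (camera adjusted p = 0.397), of 28 decidualization markers 9 rose and 7 fell (adjusted p = 0.397), and of 25 progestin and glucocorticoid receptor targets 8 rose and 5 fell (adjusted p = 0.477). Interferon-stimulated genes split evenly, with 9 rises and 9 falls of 40 (adjusted p = 0.748): OAS3 rose by 1.10, IFIT1 fell by 0.95 and XAF1 fell by 0.96. Extracellular matrix genes had 8 rises and 13 falls (adjusted p = 0.529), with COL14A1 at -1.40 and COL3A1 at -1.02. The NRF2 response had 3 rises and 12 falls (adjusted p = 0.11), with CAT at -0.97 and NQO1 at -0.83. Lysosome genes had 7 rises and 16 falls (adjusted p = 0.333), angiogenic factors 10 and 7 (adjusted p = 0.421), estrogen receptor targets 3 and 4 (adjusted p = 0.772) and alternatively activated macrophage genes 10 and 6 (adjusted p = 0.429). The median, mean and test differed in sign for the last of these and for the progestin and glucocorticoid receptor targets. Probes of LCP1, SREBF2 and GPER1 gave opposite calls within each gene.

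In total 6097 probes rose and 6412 fell (37.0%), or 3142 and 3418 genes. These changes are relative to the bulk of the probes, whose median moved by 0.69 upward without hormone and by 0.42 with hormone when arrays were scaled to the bacterial spikes. The same scaling moved the median by 0.185 for hormone without medium, by -0.0733 for hormone with medium and by -0.255 for the interaction. Under that scaling 5419 of the 12509 called probes changed sign, and 877 of them were called in the opposite direction, with 27881 rises and 223 falls in all. Arrays with and without the medium also lay in different runs of slides, so medium and run cannot be told apart by the design.

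**Figure D2:**
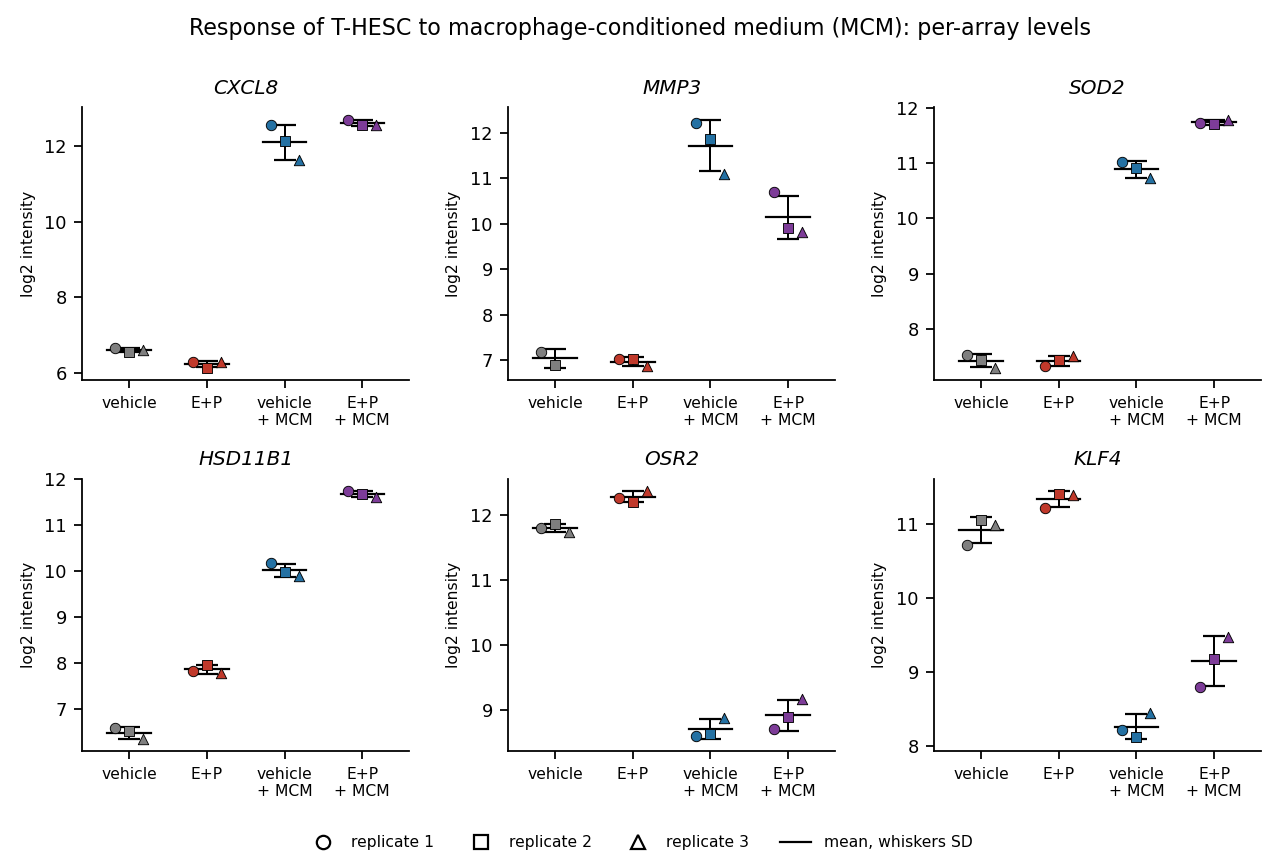
Log2 normalized intensity of 6 genes in the 4 T-HESC groups, with 1 point per array (shapes mark replicates), lines at the means and whiskers of 1 SD. CXCL8, MMP3, SOD2 and HSD11B1 were higher and OSR2 and KLF4 lower with macrophage-conditioned medium in both hormone states, relative to all probes.

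In hormone-treated cells the medium raised CXCL8 by 6.37 (SE 0.15, 2 of 3 arrays without medium above background) and CEMIP by 4.96 (SE 0.12, also 2 of 3). SOD2 rose by 4.32 (SE 0.09), CHI3L2 by 3.90 (SE 0.16) and HSD11B1 by 3.81 (SE 0.09). The largest falls were those of OSR2 (-3.37), LRRC17 (-3.18), TMEM35A (-3.16), AMOT (-2.28) and FLJ14054 (-2.25). MMP3 (3.17), MMP1 (2.82), IL6 (1.18), ICAM1 (0.63) and CCL2 (1.96) rose here too, MMP3 and MMP1 by less than without hormone. TNFAIP6 rose by 1.01. CXCL2 was at least 4.21-fold and SERPINB2 at least 3.91-fold higher. IGF1 fell by 1.82 (SE 0.15) and PGR fell by 1.28 (SE 0.14), with HOXA10 at -1.35 and DDIT3 at -1.63. LIF (-0.15), MX1 (0.08) and PTGS2 (0.17) were not called, while VEGFA fell by 0.25 (adjusted p = 0.0296). The VEGFA call was lost without any 1 of the hormone replicates 1 (0.0630), 2 (0.0636) and 3 (0.0865) or of replicates 1 (0.138) and 2 (0.0670) of hormone with medium, over a range of 0.00818 to 0.138.

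The lists that passed here and kept their call with an estimated correlation were NF-kB targets (19 higher and 1 lower; adjusted p = 1.91e-08), chemokines (11 and 0; 3.41e-07), cholesterol synthesis (15 and 0; 3.5e-06), immediate early genes (13 and 2; 7.26e-05), cytokines (9 and 0; 0.00204), metallothioneins (3 and 0; 0.00214), classically activated macrophage genes (6 and 0; 0.00522) and metalloproteinases with the plasminogen system (12 and 5; 0.0112). Adjusted over the list alone, the counts were 20 and 1 for NF-kB targets, 4 and 0 for metallothioneins, and 14 and 7 for metalloproteinases. The cholesterol genes included INSIG1 (1.54). Cell cycle genes had 27 rises and 0 falls (28 and 0 adjusted over the list alone; adjusted p = 8.71e-08, adjusted p = 0.232 with an estimated correlation), including RRM2 (1.29) and MCM5 (1.26). Contractile and TGF-beta response genes had 13 rises and 2 falls (14 and 2 adjusted over the list alone; adjusted p = 7.79e-05, adjusted p = 0.0961 with an estimated correlation). Hypoxia genes had 18 rises and 4 falls (19 and 6 adjusted over the list alone; adjusted p = 0.000444, adjusted p = 0.113 with an estimated correlation). The amino acid and ER stress response had 5 rises and 14 falls (5 and 15 adjusted over the list alone; adjusted p = 0.000455, adjusted p = 0.236 with an estimated correlation). The median, mean and test differed in sign for progestin and glucocorticoid receptor targets, the NRF2 response, decidualization markers and angiogenic factors. In all 4221 probes rose and 4704 fell (26.4%), or 2408 and 2636 genes. Scaled to the spikes, 14857 rose and 340 fell, and 2574 of the called probes changed sign. Across probes the medium effects in both hormone states correlated with Pearson r 0.784 and Spearman rho 0.704, and 6260 of the 6325 probes called in both moved the same way (1651 expected).

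The interaction asked whether the hormone effect differed between cells with and without macrophage-conditioned medium. PTX3 showed the largest positive interaction (3.19, SE 0.35, adjusted p = 4.29e-05), followed by CHI3L2 (3.10, SE 0.23, adjusted p = 5.98e-07): their group means on the log2 scale were 8.59 and 6.40 with vehicle, 8.17 and 6.74 with hormone, 7.79 and 7.19 with medium, and 10.57 and 10.64 with both. SIPA1L2 (2.10, SE 0.13), NPTX1 (1.93, SE 0.17) and DKK2 (1.90) followed among the genes picked for the size of the change. For SIPA1L2, NPTX1 and DKK2 hormone lowered the gene without medium. With the medium the fall was smaller for NPTX1. For SIPA1L2 and DKK2 the interaction exceeded the size of the fall, so that no fall remained with the medium. DHRS3, which encodes a retinal reductase, showed the largest negative interaction (-2.32, SE 0.30), followed by FLJ14054 (-2.04), TP53I3 (-1.79), IGF1 (-1.74, SE 0.21) and the WNT antagonist gene DKK1 (-1.70, SE 0.16). IGF1 and DKK1 rose with hormone without the medium, by 1.71 and 1.57. PGR showed no called interaction (0.44, adjusted p = 0.302).

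Chemokine genes had 5 positive and 0 negative interactions (7 and 0 adjusted over the list alone; adjusted p = 2.14e-05, adjusted p = 0.0203 with an estimated correlation), with CCL5 at 0.98 and CCL8 at 1.98 (above background on 1 of 3 vehicle arrays). CXCL2 was called as well, with 0 of 6 arrays without the medium above background, so that its size is not given. The list of LXR targets and lipid handling had 4 and 0 (5 and 0 adjusted over the list alone, camera adjusted p = 0.00106, adjusted p = 0.0492 with an estimated correlation), with FABP4 at 1.74, MYLIP at 0.97 and FABP5 at 0.91. Metalloproteinases and the plasminogen system had 0 and 5 (2 and 8 adjusted over the list alone; adjusted p = 0.00106, adjusted p = 0.0387 with an estimated correlation), with SERPINE2 at -1.22. Cholesterol synthesis (3 and 1; 11 and 2 adjusted over the list alone; adjusted p = 0.00106, adjusted p = 0.151 with an estimated correlation) and the NRF2 response (3 and 0; 5 and 1 adjusted over the list alone; adjusted p = 0.0115, adjusted p = 0.069 with an estimated correlation) lost their call with the estimated correlation. The NRF2 genes included GCLC (1.13). Other called genes were STC2 (1.69), PTGES (1.22), TNFAIP6 (1.03), SOD2 (0.85), DIO2 (-1.45), SGK1 (-1.26), MGP (-1.26) and PER1 (-0.83). The interaction of TSC22D3 was -0.92, a call lost with the deposited normalized intensity (0.0800, in a range of 0.000812 to 0.0800).

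Interactions were called for 718 probes, 413 positive and 305 negative (2.12%), or 258 and 191 genes. The absolute hormone effect was smaller with the medium for 403 of them and larger for 315, and 46 had called hormone effects of opposite sign. The count dropped to 427 without hormone replicate 2 and to 474 without replicate 1 of hormone with medium. Positive values made up 57.5% of the calls, 70.0% with the deposited normalized intensity, 38.4% at a log2 change of at least 1 and 14.4% (21 of 146) with scaling to the spikes. The median, mean and test differed in sign for NF-kB targets, progestin and glucocorticoid receptor targets, metallothioneins, alternatively activated macrophage genes, extracellular matrix genes and steroid hormone receptors.

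**Figure D3:**
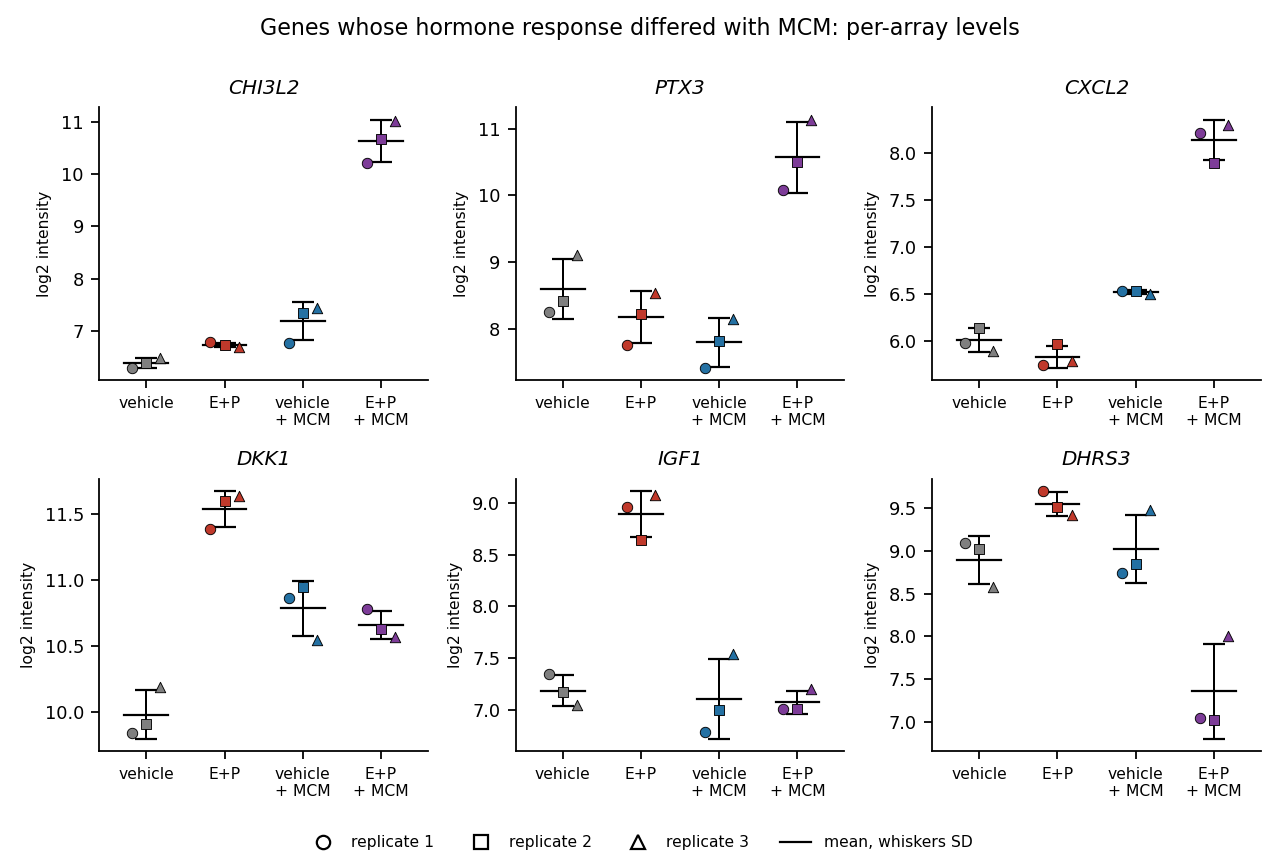
Log2 normalized intensity of 6 genes with called interactions in the 4 T-HESC groups, with 1 point per array (shapes mark replicates), lines at the means and whiskers of 1 SD. CHI3L2, PTX3 and CXCL2 (above background on 0 of 6 arrays without the medium) were highest with hormone and medium together, whereas the hormone effect on IGF1, DKK1 and DHRS3 was lower with the medium than without it.

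**Figure D4:**
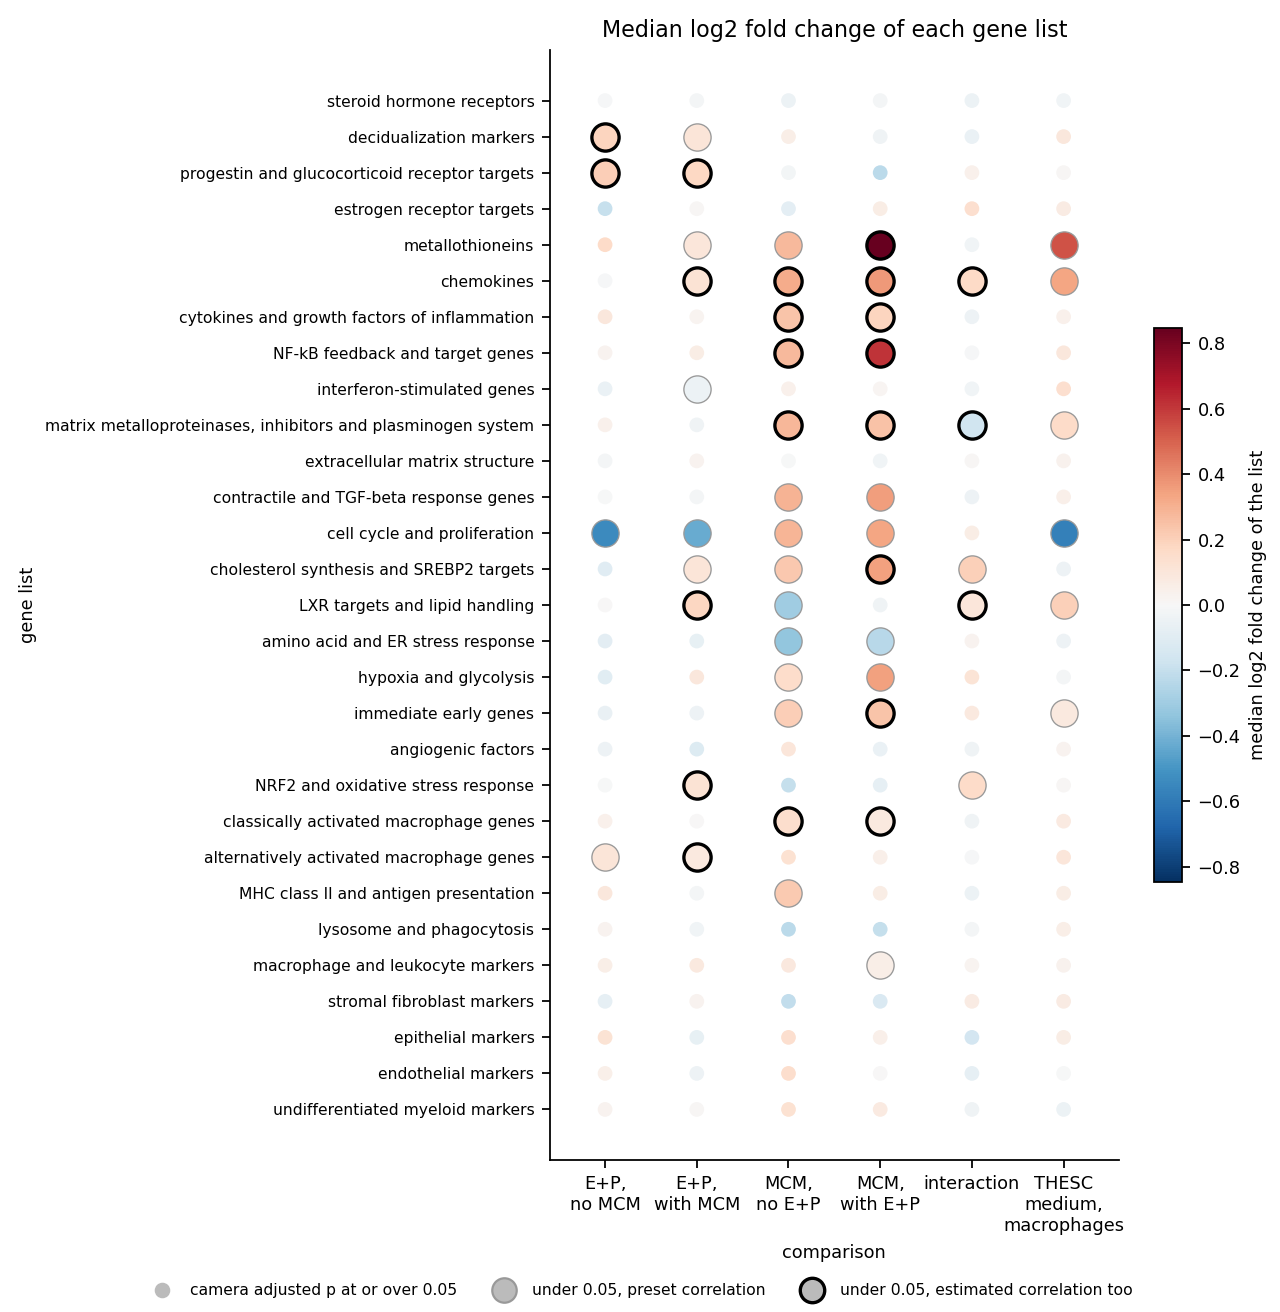
Median log2 fold change (colour) of each gene list (vertical axis) in 6 comparisons (horizontal axis), with large dots for a camera adjusted p under 0.05 with the preset correlation and black rings where the call also held with an estimated correlation. Cell cycle genes had a median of -0.54 with hormone, and their dots carry no ring in any of the 6 comparisons.

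Averaged over both media, hormone raised CORIN by 2.63 (SE 0.07, 6 arrays per state), INHBB by 2.56, IGFBP2 by 1.99, AOX1 by 1.94 and CHI3L2 by 1.90, and lowered NPTX1 (-2.49), ETV1 (-1.85), DOCK2 (-1.83), MMP1 (-1.75) and HBD (-1.67). CHI3L2 and NPTX1 also had called interactions. In these means 2639 probes rose and 3198 fell (17.2%), and rises were 30.8% of the calls with the deposited normalized intensity and 46.8% with scaling to the spikes. Progestin and glucocorticoid receptor targets had 14 rises and 0 falls (adjusted p = 1.31e-10, adjusted p = 0.00432 with an estimated correlation), and cell cycle genes 0 rises and 42 falls (adjusted p = 5.56e-23, adjusted p = 0.0656 with an estimated correlation). Averaged over both hormone states, the medium raised CXCL8 by 5.93 (SE 0.10), CEMIP by 4.83, MMP3 by 3.93, SOD2 by 3.89 and HSD11B1 by 3.67. It lowered OSR2 (-3.23), KLF4 (-2.42), LRRC17 (-2.37, with another probe at 0.14 and an adjusted p of 0.0241), TMEM35A (-2.36) and ADGRL3 (-2.24). In these means 7719 probes rose and 7633 fell (45.4%), whereas 28807 rose and 391 fell with scaling to the spikes, with 2634 of the calls made in the opposite direction.

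The reverse direction asked how U-937 macrophages responded to medium from T-HESC cells. AQP9, which encodes a channel for water and glycerol, rose by 1.39 (SE 0.08, 2.62-fold, n = 3 per group, probe GE53232, limma adjusted p = 0.00266). ADGRE1, an adhesion receptor gene, rose by 1.19 (SE 0.07, adjusted p = 0.00266). These were the only genes among the named calls that kept their call under every alternative run, leaving aside the added threshold of 1 on the log2 scale, which both also passed. LTBP1, which encodes a TGF-beta binding protein, rose by 1.44 (SE 0.15, adjusted p = 0.0251), the neuropeptide gene GAL by 1.37, the protein C receptor gene PROCR by 1.29 and OLR1, for a receptor of oxidized LDL, by 1.23. TNFSF15 (1.18), NMB (1.06), APOC1 (0.90) and the amino acid transporter gene SLC16A10 (0.90) were the other large rises. RRM2, for a ribonucleotide reductase subunit, fell by 1.32 (SE 0.15, 2.49-fold, probe GE59846, adjusted p = 0.0266). The kinetochore genes SPC25 (-1.24) and ZWINT (-1.21), IL32 (-1.05, SE 0.12), the replicative helicase gene MCM4 (-0.96) and the leukotriene receptor gene CYSLTR1 (-0.92) fell too. DUT (-0.88), CLECL1 (-0.87), LRRCC1 (-0.81) and CCNA2 (-0.80) also fell.

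Of 50 cell cycle genes 5 fell and 0 rose over all probes, and 36 fell when adjusted over the list alone (median -0.58, camera adjusted p = 2.91e-25, adjusted p = 0.458 with an estimated correlation). With fry on all 6 arrays the cell cycle list lost its call (adjusted p = 0.0609). The list stayed low without control replicate 1 (median -0.46, camera adjusted p = 2.13e-27 with the preset correlation), where no estimated correlation was tried. The list of LXR targets and lipid handling had 2 rises and 0 falls among 24 (8 and 0 adjusted over the list alone, camera adjusted p = 0.000394, adjusted p = 0.279 with an estimated correlation), and 1.41e-05 without that array. Its member ABCA1, an LXR target, had a negative value, given below. Of 5 metallothioneins 0 were called over all probes and 3 rose adjusted over the list alone (median 0.54, adjusted p = 0.00604, adjusted p = 0.393 with an estimated correlation), and 0.000158 without that array; MT1X was at 1.15 (adjusted p = 0.0518, with alternatives from 2.1e-07 to 0.312). Chemokines had 0 calls over all probes and 2 rises among 17 adjusted over the list alone (adjusted p = 0.0386, adjusted p = 0.665 with an estimated correlation). On control replicate 1 the chemokine list median lay at -1.03 from the mean of the 6 arrays, against 0.0880 and 0.0261 on the other controls, and without that array the adjusted p was 0.970. Likewise lost without it were metalloproteinases and the plasminogen system (0 calls among 25, 4 rises adjusted over the list alone; adjusted p = 0.00246, adjusted p = 0.665 with an estimated correlation, 0.532 without the array) and immediate early genes (0 calls among 28, 7 rises and 2 falls adjusted over the list alone; adjusted p = 0.0488, adjusted p = 0.458 with an estimated correlation, 0.130 without the array). Interferon-stimulated genes, with 0 calls among 40 and an adjusted p of 0.133, passed as lower without it (0.0374) but as higher with the passage block (0.0251) and with median scaling (0.0378). Over the alternatives run for these lists, adjusted p ranged from 5.15e-29 to 0.458 for cell cycle genes, from 1.41e-05 to 0.279 for LXR targets and from 0.000158 to 0.393 for metallothioneins. It ranged from 0.00263 to 0.970 for chemokines, from 5.16e-05 to 0.665 for metalloproteinases, from 0.008 to 0.458 for immediate early genes and from 0.0251 to 0.846 for interferon-stimulated genes.

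The tested reporter genes of this comparison were not called. They were TNF (-0.39, adjusted p = 0.154), CXCL8 (0.59, adjusted p = 0.416), CCL2 (-0.14), MMP9 (0.02), VEGFA (-0.01), CD163 (0.17), ABCA1 (-0.28), HMGCS1 (-0.15) and HLA-DRA (0.41, with 2 of 3 control arrays above background). Large but uncalled values included CCL20 (1.91, adjusted p = 0.114) and FN1 (1.53, adjusted p = 0.185). Without control replicate 1, CCL20 was called at 1.32 (adjusted p = 0.000139, alternatives from 2.1e-07 to 0.406), FN1 at 0.91 (0.00225, from 5.3e-06 to 0.490) and ABCA1 at -0.49 (0.00971, from 0.00512 to 0.740). Classically activated macrophage genes (adjusted p = 0.133), alternatively activated ones (0.133), the lysosome list (0.0562), MHC class II (0.35), NF-kB targets (0.269), cytokines (0.492) and cholesterol synthesis (0.56) were not called as lists. The lysosome list passed as higher with cyclic loess (0.0199) and median scaling (0.00263), in a range of 0.00263 to 0.508, and alternatively activated genes passed with the mean of all probes (0.0371) and median scaling (0.031), in a range of 0.031 to 0.643. Decidualization markers (camera adjusted p = 0.0754) passed as higher with fry (0.0126), the mean of all probes (0.0414) and median scaling (0.0395). Extracellular matrix genes (camera adjusted p = 0.133) passed as higher with fry (0.00864). Both lists were at 0.458 with an estimated correlation. The median, mean and test differed in sign for progestin and glucocorticoid receptor targets, hypoxia genes and macrophage markers.

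In limma 35 probes rose and 25 fell of 30694 (0.196%), or 23 and 21 genes, and 4473 had an unadjusted p under 0.05. The 60 calls became 808 (375 higher and 433 lower) without control replicate 1, with all 60 among them, and 12, 10, 5, 3 and 3 without control replicates 2 and 3 and treated replicates 1, 2 and 3. With the passage block 9 probes were called, 8 higher and 1 lower. Of the 21 named calls, 7 remained with the block (LTBP1, AQP9, GAL, PROCR, ADGRE1, TNFSF15 and NMB) and 0 of these were lower. Median scaling left 15 calls, all higher.

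**Figure D5:**
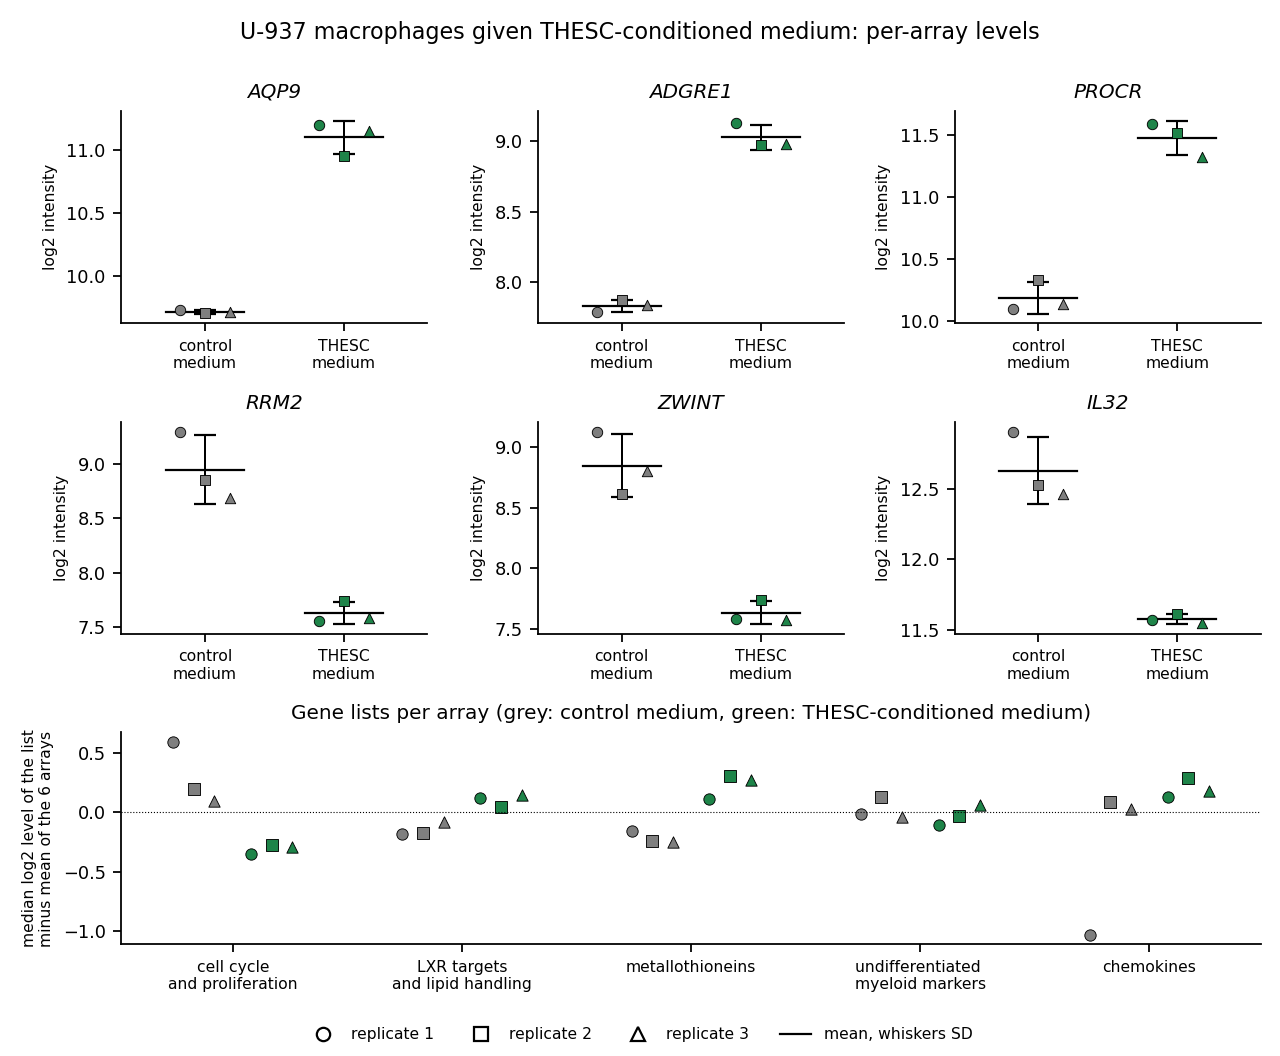
Log2 normalized intensity of 6 genes on the macrophage arrays (shapes mark replicates, lines are means, whiskers 1 SD), and the median of 5 gene lists on each array relative to the mean of the 6 arrays. Control replicate 1 stood apart for chemokines, at -1.03, whereas the cell cycle list was lower with T-HESC-conditioned medium with or without that array.

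The calls in both directions of exchange were compared over 14377 genes tested in both cell lines. Medium from the other cell type moved 8 genes the same way, against 7.77 expected. The 6 shared rises were GPAT3, LINC00690, LTBP1, OLR1, SLC16A10 and TNFSF15 (Fisher's exact test, two-sided, p = 0.411), and the 2 shared falls were ITGA4 and TMX4 (Fisher's exact test p = 0.551). Names outside the rule are given here after their values were seen, because the overlap is small.

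Cell type markers were measured in both lines. Of 27 macrophage and leukocyte markers 25 were above background on all macrophage arrays and 12 on all T-HESC arrays. Of 23 stromal fibroblast markers 20 were above background on all T-HESC arrays and 12 on all macrophage arrays. Epithelial markers numbered 7 of 19 in T-HESC and 8 in macrophages, endothelial markers 8 of 16 and 9, and undifferentiated myeloid markers 3 of 14 and 12. With macrophage-conditioned medium and no hormone, 6 macrophage markers rose and 2 fell among 15 tested (adjusted p = 0.133), 3 stromal markers rose and 10 fell among 22 (adjusted p = 0.0909, and 0.021 with median scaling, over alternatives from 0.00674 to 0.431), and epithelial (adjusted p = 0.333), endothelial (0.397) and undifferentiated myeloid markers (0.397) were not called. With hormone present, macrophage markers passed with 4 rises and 0 falls (4 and 1 adjusted over the list alone; adjusted p = 0.0359, adjusted p = 0.0961 with an estimated correlation). Among these genes, SRGN and ARHGDIB rose by 1.62 and 1.01. In hormone-treated cells without medium, stromal markers had 6 rises and 6 falls (adjusted p = 0.828).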

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

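Among the tests below, those of a common shift of all probes, of macrophage RNA carried over, and of picking probes for a large hormone effect were chosen after the result was seen, as was the scaling to bacterial spikes; the test of slide runs was written before.

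The hormone effect differed between cells with and without macrophage-conditioned medium, by the interaction term in limma, at 718 probes. The largest differences by rule were PTX3 (3.19), CHI3L2 (3.10), SIPA1L2 (2.10), NPTX1 (1.93) and DKK2 (1.90) on the positive side. On the negative side they were DHRS3 (-2.32), FLJ14054 (-2.04), TP53I3 (-1.79), IGF1 (-1.74) and DKK1 (-1.70). Gene lists whose interaction passed had adjusted p values of 2.14e-05 for chemokines, 0.00106 for metalloproteinases with the plasminogen system, 0.00106 for cholesterol synthesis, 0.00106 for LXR targets and 0.0115 for the NRF2 response. Cholesterol synthesis and the NRF2 response did not keep this with an estimated correlation between genes. Of 100 splits of the 12 arrays, 2 gave as many calls, the real one included. The splits exchanged hormone labels within each medium, so they stand for no hormone effect rather than an equal one in both media. They therefore cannot decide whether so many interaction calls could arise by chance. The other split gave 1600 calls: it exchanged hormone labels mostly in 1 medium, which turns the interaction into the hormone effect, a structure of the design.

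The hormone effects of all tested probes were also less spread out with the medium. Their SD, after the measurement error was taken off, was 0.1703 with the medium against 0.2045 without, a ratio of 0.832 (0.769 to 0.890 when each array was left out). A ratio of 1 would be required if the smaller effect arose only from picking probes with a large effect in 1 medium. All these ratios lay below it, which argues against that explanation. The range over left-out arrays is not a sampling interval, however, and the limit for the ratio was set after the result was seen. Counts of larger changes did not go the same way. At a log2 change of at least 1, hormone gave 149 calls with the medium and 135 without, and scaling to the spikes gave 472 and 474. Of the 718 interactions, 403 had a smaller absolute hormone effect with the medium and 315 a larger one. A weaker response to hormone in the presence of macrophage products may account for part of the smaller spread, as a hypothesis found and tested on the same arrays. The run of slides also differed between the media, and the RNA preparation or culture batch may have differed with it, so these stay open.

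The bacterial spikes, which the comparisons did not use, were lower by -0.51 in median log2 intensity on arrays with macrophage-conditioned medium. Their mean level was 1.30 with and 1.81 without the medium relative to each array's bulk of probes, with an array SD of 0.197 within groups (exact permutation test, two-sided, p = 0.00216, 6 against 6 arrays). All 6 spike transcripts moved alike, from -0.538 to -0.472. On the macrophage arrays the spikes lay near background.

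The medium moved 37.0% of the tested probes of the stromal line. If differences in labelling, hybridization or scanning between slide runs had scattered the probes, spikes of the same brightness should scatter too. Their robust SD was 0.159 times that of discovery probes (0.0409 against 0.258, from 28 and 14110 probes). Each spike value was a mean over several of the 360 spike spots, whereas a discovery value came from 1 spot. Averaging lowers the spread, so the ratio cannot decide how much those steps contributed. Averaged the same way, the spikes had a robust SD of 0.04165 between hormone states, which lie within runs. The spikes thus showed no added scatter between runs, which leaves a difference in culture or RNA preparation open. If macrophage RNA had come over with the medium, the 10 largest rises would need a median share of 580.8% and at least 9.21% of macrophage RNA, while 21 macrophage markers allowed a median of 0.115% (quartiles -0.158 to 1.19), which argues against it even though levels of lines with different RNA inputs are only roughly comparable. A shift common to all probes cannot be told apart from a difference in the spikes themselves: the spike difference of -0.514 is what more mRNA per unit of total RNA with the medium would give, and also what a smaller spike addition in that run would give. Products of the macrophages or residual phorbol ester in their medium could both raise genes such as CXCL8 and MMP3, and no array separates them.

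For the comparisons of 3 against 3 arrays there are only 10 splits, too few for a share under 0.05. In each of them 1 split gave as many calls, the real one. The real counts were 4688 and 2147 for hormone without and with medium, 12509 and 8925 for the medium without and with hormone, and 60 for the macrophages, and the highest other split gave 0 calls in each. For the mean effects, 1 of 100 splits gave as many calls, the real one, with 5837 against at most 2712 for hormone and 15352 against at most 3781 for the medium. That share is under 0.05 for splits made without regard to passage. Splits that keep arrays of the same passage together were not run apart.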

How the results depend on the processing

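Among the tests below, those scaled to the bacterial spikes, those of macrophages without control replicate 1 with the passage block, and the list tests and overlap without that array were chosen after the data were seen.

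For named genes 15262 values under alternatives kept their direction and side of the threshold, 781 lost the call, 77 gained it and 32 uncalled values changed sign; scaling to the spikes was run on counts only. For gene lists the numbers were 1258, 48, 68 and 47. The last number covers lists not called in the main test. It includes interferon-stimulated genes in macrophages, which passed as lower without control replicate 1 (camera adjusted p = 0.0374). Where calls of named genes were lost, the cause was not tested. With a log2 change of at least 1 required as well, 135 and 149 probes were called for hormone without and with medium, 548 and 550 for the medium without and with hormone, 112 for the interaction, 85 and 477 for the mean effects of hormone and medium, and 15 for macrophages, since that threshold is stricter. Scaling to the spikes gave 474 and 472 calls for hormone, 28104 and 15197 for the medium, 146 for the interaction, and 795 and 29198 for the mean effects. The spikes varied between arrays of 1 group and were lower with the medium. With the floored raw intensity 473 interactions were called; the cause was not tested.

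The macrophage count of 60 became 93 with the floored raw intensity, 15 with median scaling, 93 with a trended robust variance, 494 with array weights, 9 with the passage block and 1248 without control replicate 1 with the block. The passage block changed no T-HESC count by more than 1.5 times.

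When each array was left out, counts ranged from 2312 to 5127 and from 1379 to 2257 for hormone without and with medium, from 427 to 806 for the interaction and from 3 to 808 for macrophages. The cause was not tested beyond control replicate 1. The correlation across the other treatment ranged from 0.387 to 0.518 for hormone effects and from 0.762 to 0.786 for medium effects, and was 0.563 and 0.820 over probes called in either.

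The gene list tests made 70 calls, 30 with an estimated correlation and 124 with fry, which asks another question. The overlap of 8 genes was 1 with the threshold of 1, 4 with the medium effect taken with hormone, and 126 without control replicate 1 (97.3 expected). Signal over background limits dim probes: 58.8% to 64.2% of T-HESC and 56.8% to 62.9% of macrophage probes were above it.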

Other observations

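Among the tests in this part, that of undifferentiated cells, those without control replicate 1 in the overlap, and that of opposite directions were chosen after the result was seen; the test of control replicate 1 as the source of the lower cell cycle genes was written before.

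Both conditioned media moved some genes in opposite directions in the cell that received them. Of the 14377 genes tested in both lines, 9 rose in T-HESC and fell in macrophages (CCNA2, DUT, ESCO2, IL32, MCM4, PBK, RRM2, SPC25 and ZWINT), where 3.44 were expected (Fisher's exact test, two-sided, p = 0.00281). Apart from IL32, these are genes of DNA replication and mitosis. Fisher's exact test takes genes as independent, whereas the cell cycle list lost its call in both lines with an estimated correlation between genes. The p values of this overlap therefore overstate the evidence. The same 9 genes were found with hormone present (2.62 expected, Fisher's exact test p = 0.000357). Without macrophage control replicate 1 there were 95 such genes (51.0 expected, Fisher's exact test p = 1.16e-10), but shared rises then passed too (Fisher's exact test p = 0.000277, with 126 genes moving the same way where 97.3 were expected). The overlap rests on macrophage falls that some settings did not call: of the 11 named falls, 0 kept their call with the passage block, with median scaling or without any 1 of the treated replicates. The 3 genes that fell in T-HESC and rose in macrophages were APOC1, MR1 and REEP1, and the names in this paragraph were chosen after their values were seen.

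Lower cell cycle genes in macrophages given T-HESC-conditioned medium did not rest on control replicate 1 as a whole. The median of the list was -0.582 with all 6 arrays and -0.461 without that array, with 46 of 50 genes lower. Fewer undifferentiated U-937 cells in the treated cultures cannot be told apart from a change within the macrophages: the median of 12 markers of such cells was -0.0473 (quartiles -0.260 to 0.0863), but most of these markers were bright in the control cultures, which would hide the loss of a small share. A further arrest of proliferation by T-HESC products may explain the difference. The call of the list, however, ended with an estimated correlation between genes (camera adjusted p = 0.458) and with fry (adjusted p = 0.0609). The composition of the control medium was not tested.

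HSD11B1, which encodes the enzyme that regenerates cortisol, rose with each treatment alone, by 1.38 with hormone and 3.53 with the medium. PGR, in contrast, was lower with each treatment alone, at -0.84 with hormone and -1.72 with the medium.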
